A study of Mus musculus with 13 samples.

How the data were processed

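ChIP-seq was performed on neural progenitors derived from mouse ES cells, after 2 days in suspension and 3 further days with retinoic acid, per the labels' protocols. Replicate 1 of Nkx6.1 and Olig2 came from the YFP3.1 line, and replicate 1 of Nkx2.2 and replicate 2 of all ventral factors came from a derivative of it with a FLAG-tagged Gli1 at Rosa26, per the labels. Gli3 came from a V6.5 derivative tagged at the Gli3 start codon. Crosslinked chromatin was sonicated and precipitated with factor antibodies, antibody cocktails for Nkx2.2 and Nkx6.1, or anti-FLAG for Gli3. Samples were grouped by factor and by ChIP or input from their titles.

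The submitters' processing notes name Bowtie2 2.2.4, HOMER and the build mm9. Which of them made a given file, with which settings and filters, and whether replicates were pooled is not given in the sources used here. The authors deposited the peak lists as 3 columns (chromosome, start, end) without a score, under the replicate 1 samples and the Gli3 sample, so no threshold could be made stricter. The deposited coverage tables hold, per the file headers, offsets up to 2000 bp on each side of the peak centre in steps of 25 bp, repeated in 3 blocks that name no library. The name of each table carries 3 library codes, the last of them shared by the Nkx6.1 and Olig2 tables. If their order is that of the blocks, which the sources used here do not state and which was not assumed, block 3 of these 2 tables would be 1 library; the labels name 1 sample for both factors, an input, and the mean over the blocks would then include it. Low values of each block (up to 20 steps, where a step is its smallest value above 0) are whole multiples of its own step within 0.02 of a step, so the authors' tables appear scaled per library, but depth is unknown and the scaling is not given. Coverage was therefore tested within a table. The 1 exception, chosen after seeing the data, grouped Nkx2.2 and Olig2 peaks by block 3 coverage at the centre over the flank (each + 1), which rests on a common scale that is not known, and it is not used to decide anything. Columns of other samples left out numbered 0.

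The coordinates were taken as deposited and printed 1-based. The gene table at hand is for GRCm38, another build, where 100 peaks of chromosome 7 alone would end beyond its last gene. No annotation or genome of mm9 was used here, so assignment to genes, distance to transcription start sites and motif searches, all planned, were not run, and no gene is named at a region. The rule for named regions, fixed before the data were examined, took the first 10 regions of 4 factors and the first 5 of the 3 ventral factors by position (no score being given), and the 2 windows of 100 kb with most peaks per list. Its parts that need scores, genes or named ChIP libraries could not be applied. Regions outside the rule are said to be chosen after their values were seen.

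A table row was matched to the peak on the same line of the list. This was checked with peaks of 1 list within 1000 bp of each other, whose shifted profiles must agree: their median correlation was 0.978 to 0.999 over the tables and blocks, and near 0 with rows shuffled (-0.0846 to 0.133).

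Peaks overlapped when they shared at least 1 bp. Overlap was tested against 10000 circular shifts of 1 list within each chromosome, over the span that the 4 lists cover, two-sided, with Benjamini-Hochberg adjustment over 6 pairs. Regions were unions of overlapping peaks. Gli3 at region classes was compared by Fisher's exact test with conditional odds ratios and 95% intervals, adjusted over 10 comparisons, of which the planned ones were those by number of factors. A further factor at regions of a pair was compared in the same way without adjustment, which was not planned. Counting 4 lists together gave 70 regions of 4 factors, and 69 of the 550 regions of 3 ventral factors were overlapped by Gli3 directly. The planned ratio of ChIP replicates over input could not be computed with libraries unnamed. In its place coverage was averaged within 250 bp of the centre and in the outermost 250 bp on each side (the flank), per block, and co-bound and singly bound peaks were compared on log2(coverage + 1) averaged over the blocks by a permutation test with 100000 resamples. Alternatives were centres within 100 or 1000 bp, local shifts, 100 random subsets of the shortest list's size, a window of 100 bp, a pseudocount of 0.1, blocks scaled to 1 flank median, and, chosen after seeing the data, single blocks, leaving out blocks, leaving out the 10% of peaks with the highest block 3 coverage, and leaving out chromosomes 8 and Y.

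The tests were tried on simulated data, with 200 shifts or resamples in each test. Simulated peaks were placed independently and evenly along the chromosomes, and simulated values were independent normal draws. The real peaks crowd together and close neighbours share coverage, so the rates of calls below need not hold for the real lists. With 100 planted overlaps in lists of the real lengths, a mean excess of 98.9 to 100.5 was recovered over the 6 pairs, and every simulated pair was called. With nothing planted, a first set of 20 simulations called 4 for Nkx2.2 and Olig2, and a first set of 50 called 13 for the mean difference at the size of the Olig2 table, more than a threshold of 0.05 should give. Neither set was discarded. The same random stream was continued, and over 200 simulations per pair 1.0% to 4.5% were called, while 4.9% of 1000 were called for Nkx2.2, 4.4% for Nkx6.1 and 5.5% for Olig2. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.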

Results

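Binding of 4 transcription factors was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in neural progenitors made from mouse embryonic stem (ES) cells. Nkx2.2, Nkx6.1 and Olig2 are transcription factors of the ventral neural tube that take part in dividing its progenitors into domains. They were profiled in ventral progenitors, which received 500 nM retinoic acid together with 160 to 800 nM of a Smoothened agonist, a compound that switches on Sonic hedgehog signalling. Gli3, a transcription factor that acts downstream of Sonic hedgehog, was profiled in progenitors made without the agonist, which the labels call dorsal. Its protein carried a FLAG tag in another ES cell line, so the factor, the culture and the line cannot be separated in any comparison with Gli3. The labels describe 13 libraries, of which 7 were ChIP libraries and 6 inputs (sequenced chromatin without immunoprecipitation). Each ventral factor had 2 ChIP libraries and Gli3 had 1.

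The values analysed were 4 peak lists, 1 per factor, and 3 tables of coverage around the peaks of the ventral factors. The Olig2 list held 11747 peaks, the Nkx2.2 list 5551, the Nkx6.1 list 4094 and the Gli3 list 1888. Every peak was 300 bp wide, and no peak carried a score or a gene name. Positions are on the mouse build mm9 throughout, and which genes lie at or near them was not analysed here. Read depth per library is unknown. As there was 1 list per factor, tests of overlap compare these lists with shifted copies of them, not cultures with each other, and confidence intervals cover counting error only.

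The first question was whether the 3 ventral factors bound the same places. They did so far more often than lists moved at random along each chromosome. Of the 4094 Nkx6.1 peaks, 1580 (38.6%, 95% Wilson interval 37.1 to 40.1) shared at least 1 bp with an Olig2 peak, 135.3-fold over the mean of 11.7 in 10000 circular shifts. Of the 5551 Nkx2.2 peaks, 1348 (24.3%, 23.2 to 25.4) overlapped an Olig2 peak, 84.4-fold over the shifted mean, and 896 (16.1%, 15.2 to 17.1) overlapped an Nkx6.1 peak, 160.7-fold over it. Seen from the longest list, 13.5% of Olig2 peaks overlapped Nkx6.1 and 11.2% overlapped Nkx2.2. In each of the 6 pairs of lists the two-sided permutation p was 0.0002, the smallest that 10000 shifts can give, and 0.0002 after Benjamini-Hochberg adjustment over the 6 pairs. Against local shifts of 10 to 100 kb, the folds of the 6 pairs were lower but still lay between 39.5 and 90.8. Such shifts keep the crowding of peaks over wider regions, but not over distances shorter than the shift.

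The overlapping peaks were close to superimposed. The median distance between centres was 45 bp for Nkx6.1 peaks at Olig2 peaks, 52.5 bp for Nkx2.2 at Nkx6.1 and 71 bp for Nkx2.2 at Olig2. Centres within 50 bp made up 53.99%, 48.2% and 37.98% of the overlapping peaks in these pairs, where an even spread of distances would give 16.9%. The excess fell steeply with distance. Between 300 and 1000 bp it was 7.02-fold for Nkx6.1 peaks next to Olig2, 6.71-fold for Nkx2.2 next to Nkx6.1 and 5.11-fold for Nkx2.2 next to Olig2. From 20 to 100 kb, Nkx6.1 peaks had their nearest Olig2 peak 0.695 times as often as in shifted lists (p = 0.0002 by the permutation test), a range that leaves out peaks with a nearer neighbour. The same ratio was 0.881 for Nkx2.2 peaks next to Olig2 (permutation p = 0.0002) and 1.05 for Nkx2.2 next to Nkx6.1 (permutation p = 0.178).

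**Figure D1:**
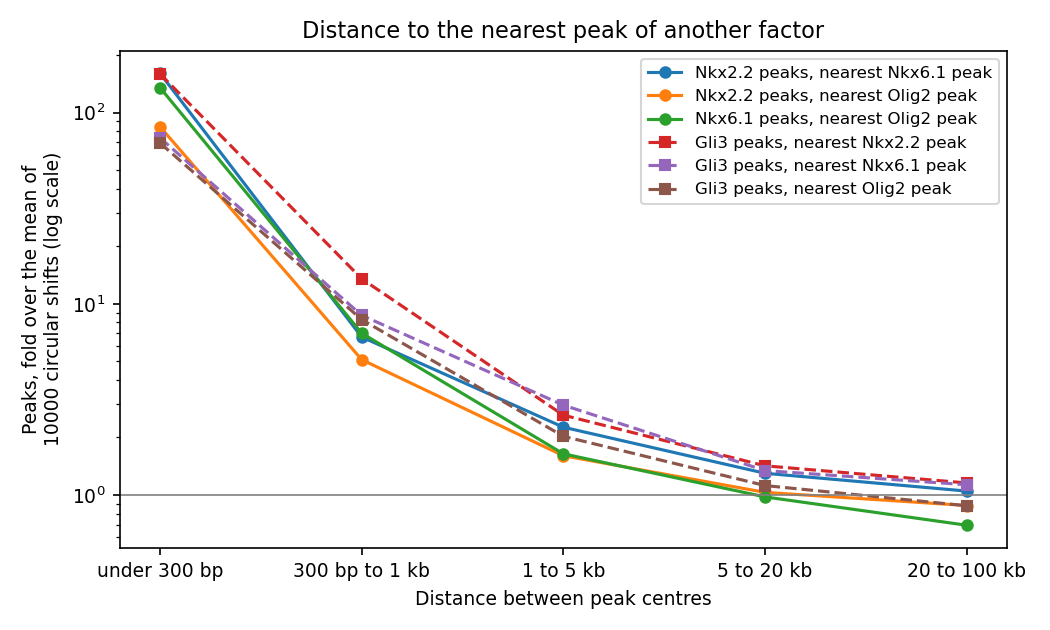
The horizontal axis gives the distance from a peak's centre to the nearest centre in another list, in 5 bins, and the vertical axis, on a log scale, gives the number of peaks in the bin over the mean of 10000 circular shifts. Points are the 6 pairs of lists, which start between 69.4 and 160.7 under 300 bp and lie between 0.695 and 1.16 from 20 to 100 kb.

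Peaks of the 3 ventral factors also fell in the same regions. Tests of a further factor at regions of a pair were chosen after seeing the data, and their p is unadjusted. The factors were precipitated separately, so shared regions do not show binding in the same cell. Joined where they overlapped, the peaks of the 3 factors formed 17913 regions, of which 15293 held 1 factor, 2070 held 2 and 550 held all 3. In 10000 shifts of the lists, at most 2 such regions of 3 factors appeared (permutation p = 0.0002). Among Nkx2.2 regions with an Nkx6.1 peak, 63.5% (60.3 to 66.7; 550 of 866) also held Olig2, against 16.4% (15.4 to 17.6; 744 of 4525) of Nkx2.2 regions without Nkx6.1, an odds ratio of 8.84 (7.52 to 10.4, Fisher's exact test, two-sided, p = 2.35e-167). Among Nkx6.1 regions, Olig2 was present at 63.5% of those with Nkx2.2 and at 31.8% (30.2 to 33.4) of those without, an odds ratio of 3.74 (3.19 to 4.39). Among Olig2 regions, 35.3% (32.9 to 37.7) of those with Nkx6.1 and 7.38% (6.88 to 7.90) of those without held Nkx2.2. Most regions nonetheless held 1 factor, with 9342 for Olig2 only, 3781 for Nkx2.2 only and 2170 for Nkx6.1 only.

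The first 5 regions of the 3 ventral factors by position all lay on chromosome 1, at 5222308 to 5223154, 9568993 to 9569303, 9574012 to 9574363, 12825566 to 12825997 and 43417543 to 43417880. Coverage there differed between the factors' tables. At 9574012 the Olig2 peak had 112.8 units in block 1 and 88.2 in block 2, the Nkx2.2 peak 21.8 and 12.1, and the Nkx6.1 peak 24.97 and 13.01. At 9568993 the Olig2 peak had 7.06 units in block 1 and 6.30 in block 2, the Nkx2.2 peak 21.2 and 4.30, and the Nkx6.1 peak 15.8 and 7.36. The blocks are described further on, and coverage is not on a scale that allows a test between tables.

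The next question was where Gli3 in dorsal-type progenitors bound relative to the ventral factors. Of the 1888 Gli3 peaks, 686 (36.3%, 34.2 to 38.5) overlapped a peak of at least 1 ventral factor. Nkx2.2 peaks were met by 22.5% of Gli3 peaks (20.7 to 24.4), 159.7-fold over the shifted mean of 2.66. Olig2 peaks were met by 20.1% (18.3 to 21.9), 69.4-fold over the shifted mean, although the Olig2 list is the longer. Nkx6.1 peaks were met by 7.36% (6.27 to 8.63), 73.9-fold over it. Median distances between centres were 72, 68 and 78 bp. Of all Gli3 peaks, 26.2% overlapped 1 ventral factor, 6.62% overlapped 2 and 3.496% overlapped 3.

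Pooled by number, regions with more ventral factors held Gli3 more often, though not in every combination of factors (below). A Gli3 peak lay at 3.17% (2.91 to 3.46) of regions with 1 ventral factor, 6.33% (5.36 to 7.46) of regions with 2 and 12.5% (10.0 to 15.6) of regions with 3. The odds ratio of 3 against 1 factors was 4.38 (3.30 to 5.75, Fisher's exact test, two-sided, adjusted p = 3.81e-20 over 10 such comparisons), and that of 3 against 2 was 2.12 (1.54 to 2.91, adjusted p = 8.13e-06). With every list drawn down to the same length the first odds ratio averaged 3.65 but was no longer past the threshold (median p = 0.198 by the exact test), since few regions of 3 factors were then left. Peaks of higher coverage, averaged over the blocks described further on, also lay at Gli3 more often. From lowest to highest quartile the share rose from 0.293% to 8.01% for Nkx6.1, 0.375% to 7.52% for Olig2 and 4.61% to 10.6% for Nkx2.2. Ranked by block 1 alone, it rose from 1.76% to 5.96% for Nkx6.1 and from 1.70% to 5.11% for Olig2. For Nkx2.2 there was no steady rise by block 1 (6.34%, 8.62%, 8.82% and 7.85%), and by block 3 the share went from 2.80% to 13.0%. Coverage and the width of regions were not held equal, so their part in the rise with the number of factors was not separated.

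The share with Gli3 also differed by which factor was present. Regions of Nkx2.2 only held Gli3 in 7.17% (6.39 to 8.03) of cases, those of Olig2 only in 2.10% (1.83 to 2.41) and those of Nkx6.1 only in 0.829% (0.525 to 1.31). The odds ratio of Nkx2.2 only against Olig2 only was 3.60 (2.97 to 4.37, Fisher's exact test, adjusted p = 6.11e-40), and against Nkx6.1 only it was 9.23 (5.71 to 15.9, adjusted p = 6.21e-34). Regions of Nkx6.1 only held Gli3 less often than those of Olig2 only, with an odds ratio of 0.390 (0.226 to 0.635, Fisher's exact test, adjusted p = 3.13e-05). This holds for that class and not for the whole list, as the class leaves out the 38.6% of Nkx6.1 peaks at Olig2. Over whole lists, Gli3 lay at 3.47% (2.95 to 4.07) of Nkx6.1, 3.26% (2.95 to 3.60) of Olig2 and 7.91% (7.23 to 8.65) of Nkx2.2 peaks. Among regions of 2 factors, Nkx2.2 with Olig2 reached 10.2% (8.24 to 12.6), Nkx6.1 with Olig2 4.55% (3.43 to 6.02) and Nkx2.2 with Nkx6.1 2.85% (1.51 to 5.32), which is below regions of Nkx2.2 only. The last 2 of these pairs did not differ past the threshold (odds ratio 0.615, 0.261 to 1.29, exact test, adjusted p = 0.257).

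**Figure D2:**
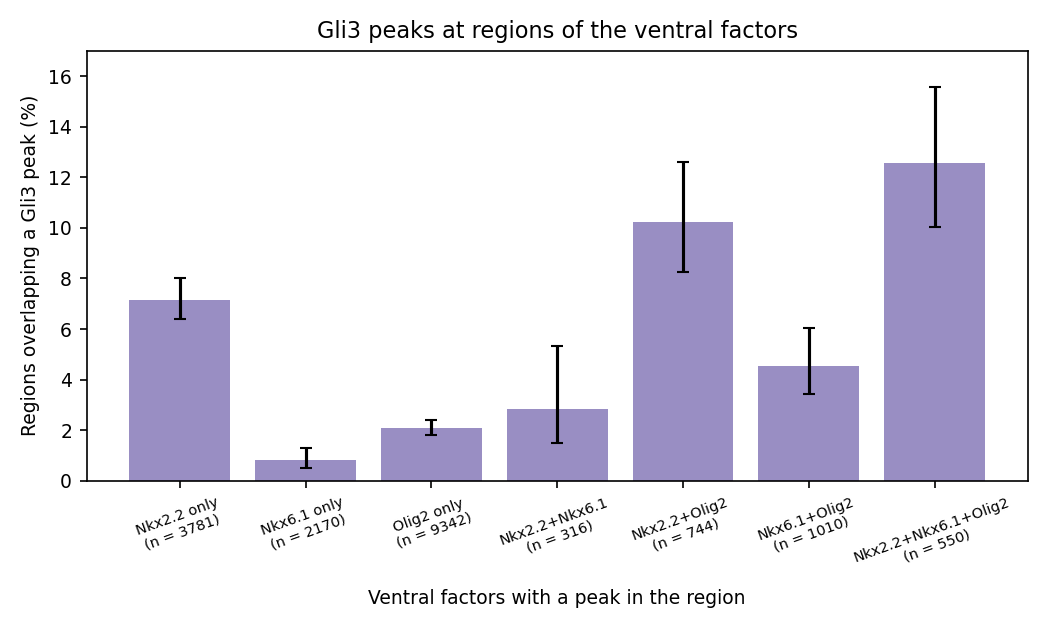
Bars give the percentage of regions that overlap a Gli3 peak, by which ventral factors have a peak in the region, with the number of regions under each bar and 95% Wilson intervals. The share is lowest at regions of Nkx6.1 only (0.829%) and highest at regions of all 3 factors (12.5%).

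Peaks of all 4 factors joined into 70 regions, against a mean of 0.313 and a maximum of 7 in 10000 shifts of the Gli3 list (permutation p = 0.0002). They lay on all autosomes and on neither sex chromosome. The first 10 by position were on chromosome 1 at 88889426 to 88889871 and 129427849 to 129428288, on chromosome 2 at 103483792 to 103484202, 105452215 to 105452764, 137531788 to 137532598, 150561578 to 150562142 and 172553672 to 172554295, and on chromosome 3 at 34340202 to 34340585, 96236036 to 96236737 and 101929404 to 101930293. The region at 150561578 on chromosome 2 had the highest block 1 coverage of these 10 in the Nkx2.2 table (162.8 units) and the Olig2 table (186.5 units), while its Nkx6.1 peak had 20.8. The highest Nkx6.1 coverage among them was 48.4 units in block 1, at 129427849 on chromosome 1.

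Peaks also gathered in larger windows. The 100-kb window from 52100001 to 52200000 on chromosome 6 held the most peaks of each ventral list, with 9 of Nkx2.2, 9 of Nkx6.1 and 10 of Olig2, and it held 6 of Gli3. Placed at random, the fullest window of a list had at most 5, 4 and 6 peaks for these factors in 95% of 1000 placements. The next window for Nkx2.2, from 96400001 on chromosome 11, held 8 of Nkx2.2, 6 of Nkx6.1, 8 of Olig2 and 1 of Gli3. The next for Nkx6.1, from 101900001 on chromosome 5, held 7 of Nkx6.1, 7 of Olig2, 5 of Nkx2.2 and 2 of Gli3. For Olig2, the first by position of the windows tied for the next place, from 146100001 on chromosome 2, held 9 Olig2 peaks with 3 of Nkx6.1, 2 of Nkx2.2 and 0 of Gli3. The fullest windows of the Gli3 list lay elsewhere, with 8 Gli3 peaks and 0 of any ventral factor from 2800001 on chromosome Y, and 7 with 5 of Olig2, 2 of Nkx2.2 and 2 of Nkx6.1 from 63600001 on chromosome 13.

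Of 21 chromosomes, 8 held a share of the Gli3 list that differed past the threshold from their share of the ventral regions, 3 of them a higher and 5 a lower one. Chromosome 8 held 14.2% (12.7 to 15.8) of the 1888 Gli3 peaks, against 5.80% of Nkx2.2, 5.54% of Nkx6.1 and 5.52% of Olig2 peaks. Against the ventral regions the odds ratio was 2.80 (2.41 to 3.24, Fisher's exact test, two-sided, adjusted p = 1.12e-36 over 21 chromosomes). Chromosome 11 was also higher in the Gli3 list (8.21% against 6.21% of ventral regions, exact test, adjusted p = 0.00381), as was chromosome Y with 12 Gli3 peaks, and 5 chromosomes were lower (1, 6, 14, 18 and X). The shares of a list are bound together, so the larger share of chromosome 8 lowers those of the other chromosomes. The comparison was not repeated without chromosome 8, so how far the 5 lower shares rest on it is not known. Chromosome X was thinly covered in every list, with peaks per Mb on the autosomes 8.78 times those on X for Nkx2.2, 5.31 times for Nkx6.1, 3.82 times for Olig2 and 8.90 times for Gli3.

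**Figure D3:**
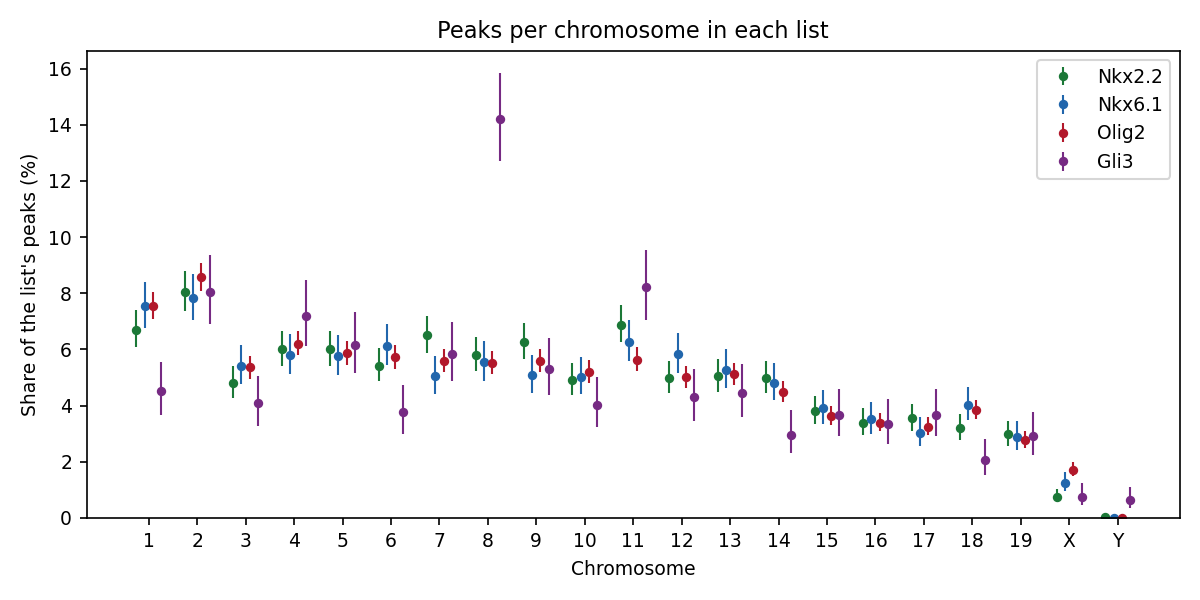
Points give the percentage of each list's peaks on each chromosome, with 95% Wilson intervals, for the 4 lists. On chromosome 8 the Gli3 list stands at 14.2% while the ventral lists lie between 5.52% and 5.80%.

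Coverage around the peaks of each ventral factor was given in 3 blocks of columns whose headers name no library, so the blocks carry numbers here and are not taken as replicates. Within 250 bp of Nkx2.2 peak centres, mean coverage was 23.8 units in block 1, 6.39 in block 2 and 1.39 in block 3, which is 25.3, 10.6 and 2.33 times the mean in the outermost 250 bp on each side. For Nkx6.1 the means were 13.5, 7.13 and 0.738 (18.4, 12.2 and 1.55 times), and for Olig2 18.3, 13.0 and 0.792 (22.2, 18.6 and 1.62 times). In every block, mean coverage dropped at the left edge only. In block 3 of Nkx6.1 it was 0.171 units at -2000 bp, 0.514 at -1800 bp and 0.530 at 2000 bp. The flank includes this edge, so ratios to the flank and shares above it are higher than without the drop. More than 2 times the flank was reached at 99.2%, 94.9% and 56.4% of Nkx2.2 peaks in blocks 1, 2 and 3, at 99.6%, 96.4% and 38.4% of Nkx6.1 peaks, and at 98.8%, 97.4% and 40.4% of Olig2 peaks. Across peaks, which are not independent replicates, the rank correlation of blocks 1 and 2 was 0.66 for Nkx2.2, 0.64 for Nkx6.1 and 0.73 for Olig2. That of blocks 1 and 3 was -0.170, 0.193 and 0.122.

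**Figure D4:**
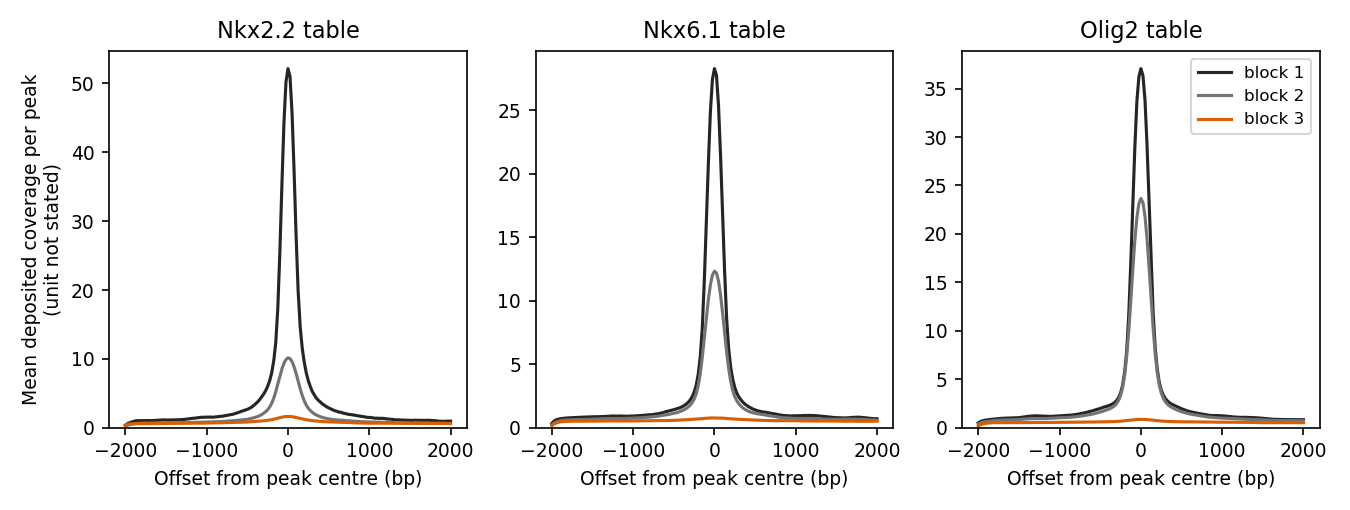
Each panel is 1 table; the horizontal axis is the offset from the peak centre in bp and the vertical axis the mean coverage over all peaks, in units that the sources used here do not state. Lines are the 3 blocks, whose mean within 250 bp of the centre runs from 23.8 down to 1.39 for Nkx2.2, from 13.5 to 0.738 for Nkx6.1 and from 18.3 to 0.792 for Olig2.

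Peaks shared with another ventral factor had higher coverage than peaks of 1 factor. On the log2(coverage + 1) scale, averaged over the blocks, the difference was 0.57 for Olig2 (3.11 ± 0.74, SD over 2357 peaks, against 2.54 ± 0.62 over 9390), 0.48 for Nkx6.1 (2.61 ± 0.54 over 1911 against 2.14 ± 0.43 over 2183) and 0.33 for Nkx2.2 (2.94 ± 0.55 over 1684 against 2.61 ± 0.45 over 3867). The permutation p was 1e-05 in each, the smallest that 100000 resamples can give, and speaks of these peaks only. The size depends on the blocks averaged: with 1 block left out it lay between 0.36 and 0.79 for Olig2, 0.32 and 0.63 for Nkx6.1, and 0.14 and 0.60 for Nkx2.2. From the lowest to the highest quartile of coverage, the share of peaks bound by another ventral factor rose from 18.3% to 76.6% for Nkx6.1, from 5.75% to 39.4% for Olig2 and from 15.9% to 51.3% for Nkx2.2. In block 3 alone the Nkx2.2 difference was reversed, at -0.21 (permutation p = 1e-05), while Nkx6.1 and Olig2 kept 0.16 and 0.13.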

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

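The tests of explanations in this part were chosen after the results were seen, except the test of list order on chromosome 8, which was set before its result was known. Lists that differ in where Gli3 lies or in how their peaks are spread stood out by tests of the difference itself.

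Gli3 peaks lay at regions of Nkx2.2 only more often than at regions of Olig2 only (odds ratio 3.60) or of Nkx6.1 only (9.23). With co-bound peaks included the gap was smaller, at 7.91% of Nkx2.2, 3.47% of Nkx6.1 and 3.26% of Olig2 peaks. Draws of 1 length gave a mean odds ratio of 2.99 for Nkx2.2 only against Olig2 only. Random draws leave the expected share of each list's peaks at a Gli3 peak unchanged. They therefore cannot decide whether the unequal length of the lists is a cause. Nkx2.2 peaks also rise more over the flank in block 3 (2.33 times in the mean, 1.62 for Olig2 peaks), and this stays open as a cause. Grouped by block 3 centre over flank, all peaks of both lists gave a Mantel-Haenszel odds ratio of 2.06 (1.78 to 2.39) against 2.55 ungrouped, but block 3 has a step of 0.245 units in the Nkx2.2 table and 0.392 in the Olig2 table, so like values there need not be like coverage, and raised block 3 coverage cannot be told apart from other causes. Against as many Olig2-only regions of the highest block 1 coverage, the odds ratio of Nkx2.2-only regions was 2.76 (2.18 to 3.51), and with all Nkx2.2 peaks, co-bound ones included, against as many of the highest Olig2 peaks it was 1.81 (1.54 to 2.14, and 2.55 before this choice). Ranked by block 1, a surplus of weak Olig2 peaks thus does not account for all of it. The ranking matters, as the highest Olig2 quartile held Gli3 at 5.11% by block 1 and at 7.52% by coverage averaged over the blocks. By that average the highest Nkx2.2 quartile held 10.6%, and all Nkx2.2 peaks held 7.91%. A preference of Gli3 for the places that Nkx2.2 binds stays open as a biological hypothesis, but antibody and library go with each factor, and the line of replicate 1 was another for Nkx2.2 than for Nkx6.1 and Olig2, and these were not separated.

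Chromosome 8 held a larger share of the Gli3 peaks than of the ventral regions (odds ratio 2.80). A few dense clusters are not enough, because without the 10 windows of 1 Mb with the highest counts of Gli3 peaks there the odds ratio was 2.14 (1.79 to 2.55). Counts in 10 of 10 equal segments lay above the ratio of the lists, by 1.09 to 4.05 times, but unevenly. The lowest had 11 Gli3 peaks against 10.1 from that ratio, and the next 9 against 7.80, so no excess can be told there. An extra copy of chromosome 8 in the cells of the Gli3 libraries may be the cause. It should add weak calls towards the end of a list ordered by strength. The last 20% of the list against the first 20% gave an odds ratio of 1.11 (0.699 to 1.76, exact p = 0.658), which decides nothing. The first 20% already held 11.6% (8.79 to 15.3) of its peaks on chromosome 8, against 5.58% of the ventral regions. The excess is thus not confined to the end of the list, but what orders the list is not given. Coverage of the Gli3 libraries was not analysed here, and the line and culture differ too, so these cannot be told apart.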

How the results depend on the processing

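The settings with blocks left out or alone, without the 10% of peaks with the highest block 3 coverage, and without chromosomes 8 and Y were chosen after seeing the data, as were the alternatives for Nkx2.2-only against Olig2-only regions and for a further factor at regions of a pair. All 36 alternatives of the pairwise overlaps stayed above shifted lists and past the threshold, with folds of 122.7 to 357.5 for centres within 100 bp, 27.3 to 58.8 within 1000 bp, 39.5 to 90.8 over local shifts, 71.6 to 165.8 in subsets of the shortest list's size, 54.8 to 161.3 without the highest block 3 peaks and 71.3 to 164.3 without chromosomes 8 and Y. Random subsets thin the observed and the shifted overlaps alike, so the folds in subsets were bound to stay near the main ones and add no support. The 6 alternatives for a further factor kept direction and threshold. Regions of the 3 ventral factors numbered 14.8 on average in subsets against 550, and regions of 4 factors 2.08 in subsets and 42 for centres within 100 bp against 70; smaller lists and a narrower rule give fewer by construction. The odds ratio of Gli3 at 3 against 1 ventral factors was 3.65 in subsets with a median p of 0.198 by the exact test, past the threshold no longer because few regions of 3 factors are left, and of the 8 alternatives for Gli3 the other 7 kept their side. The subsets for Nkx2.2-only against Olig2-only regions are among these 7 and could hardly move, so they add no support. Of 27 alternatives for co-bound peaks, 26 kept direction and threshold, and Nkx2.2 in block 3 alone was reversed at -0.21; the cause was not tested. Their size moved more: the Nkx2.2 difference of 0.33 became 0.14 without block 2 and 0.60 without block 3, that of Nkx6.1 (0.48) became 0.32 and 0.63, and that of Olig2 (0.57) became 0.36 and 0.79. The rank correlation of blocks 1 and 2 moved to 0.63, 0.60 and 0.70 (Nkx2.2, Nkx6.1, Olig2) with a window of 100 bp and to 0.60, 0.59 and 0.69 without the 5% highest signals. That of blocks 1 and 3 moved from -0.170, 0.193 and 0.122 to -0.233, 0.150 and 0.070 with a window of 100 bp, and to -0.160, 0.169 and 0.096 without the 5% highest signals. The median log2 of centre over flank per block left its interval in 23 of 27 alternatives (window, pseudocount and flank scaling), most with a pseudocount of 0.1, as for blocks 1, 2 and 3 of Nkx2.2 from 3.78, 1.87 and 0.499 to 5.77, 3.08 and 1.02; in every setting block 1 stayed highest and block 3 lowest in each table. No paired analysis was possible because the blocks carry no replicate numbers and each factor has 1 peak list. For the same reason the ratio of ChIP over input and the settings without replicate 1 or 2 were not run. The stricter peak threshold was not run as no score is given, nor were the alternatives for genes, start sites and motifs. Depth is unknown, so what depth limits could not be stated.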

Other observations

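The tests named in this part were chosen after the results were seen. The peaks with the highest coverage, chosen after their values were seen, differed in company. The highest Olig2 peak (chromosome 13, 64122241 to 64122540, 616.6 units in block 1 and 333.2 in block 2) and the highest Nkx6.1 peak (chromosome 6, 18204726 to 18205025, 338.9 and 161.2 units) each overlapped peaks of all 3 ventral factors and none of Gli3. The highest Nkx2.2 peak (chromosome 1, 120810604 to 120810903, 489.2 and 75.5 units) overlapped no peak of another list. Among the 3 highest of each table, all 3 of Olig2 overlapped every ventral factor and 2 of them also Gli3, 2 of Nkx6.1 overlapped every ventral factor while the other lacked Nkx2.2, and none of Nkx2.2 overlapped another list, though 2 of these Nkx2.2 peaks overlap each other and are 1 site.

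The company of Nkx2.2 peaks varied with their block 3 coverage. From its lowest to its highest quartile, the share with Gli3 rose from 2.80% (2.05 to 3.80) to 13.0% (11.3 to 14.8), while the share with another ventral factor was 36.6% (34.1 to 39.1) in the lowest and 13.0% (11.3 to 14.8) in the highest. In the other tables both shares rose with block 3 coverage: Gli3 from 0.488% to 8.21% and co-binding from 31.8% to 62.7% for Nkx6.1, and Gli3 from 0.952% to 7.50% and co-binding from 13.3% to 28.2% for Olig2. Block 1 coverage set Nkx2.2 peaks with Gli3 apart less, at 6.34% in the lowest and 7.85% in the highest quartile.

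The overlap of the ventral lists was weighed against technical explanations. The 10% of peaks with the highest block 3 coverage are not its whole cause, since without them the lowest fold of the 3 ventral pairs was 81.5. Block 3 was near its floor for Nkx6.1 and Olig2, with median central coverage of 0.672 and 0.710 units and a step of 0.392. Shares above the flank are therefore rough in this block. More than 2 times the flank in block 3 was reached at 38.4% or more of each list's peaks. Most such peaks thus stayed in, and raised block 3 coverage beyond the highest 10% was not excluded. Crowding of all lists into the same wider parts of chromosomes is not enough either, as the lowest fold over local shifts was 50.5. Those shifts moved every peak by at least 10 kb, so crowding over shorter distances was not weighed. Antibodies that bind more than 1 factor, and the culture conditions that the ventral factors had in common, were not tested.

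Block 3 of the Nkx6.1 and Olig2 tables is likely 1 library. At 9157 positions shared by 80 pairs of peaks from both tables, 99.2% of the values were equal within 0.001. In the other 8 pairs of blocks 0% were equal, but those blocks have unlike steps. Their values above 0 could hardly be equal, so the 0% adds no support. The only sample whose label names both of these factors is the input of replicate 2, which is a hypothesis for block 3 and was not used to name it.

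Block 3 coverage in the flanks of peaks on chromosome 8 was 1.201 ± 0.035 (SE over peaks) times the mean for Nkx2.2, 1.16 ± 0.049 for Nkx6.1 and 1.13 ± 0.029 for Olig2, where the values of the last 2 tables are not independent. Chromosome 8 does not stand alone in this: on chromosome 11 block 3 had 1.08 ± 0.033, 1.11 ± 0.048 and 1.16 ± 0.078 times the mean. On chromosome 8 block 2 had 1.06 ± 0.045, 1.11 ± 0.061 and 1.09 ± 0.106 times the mean. Block 1 had 0.938 ± 0.084, 0.920 ± 0.053 and 0.857 ± 0.060 times there. Given these errors, the block 1 and block 2 values are not all clear of the mean. On chromosome X block 3 had 0.53, 0.48 and 0.44 times the mean. The share of Gli3 peaks at a ventral peak was 35.8% (30.3 to 41.7) on chromosome 8 and 36.4% (34.1 to 38.8) elsewhere. It fell along the Gli3 list, from 47.9% (42.9 to 52.9) in the first 20% to 22.5% (18.6 to 27.03) in the last 20%, and what orders that list is not given in the sources used here.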
